A study of Homo sapiens with 3 samples.

How the data were processed

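Gene expression was measured on Visium spatial arrays, on which messenger RNA from a tissue section is captured by barcoded spots and counted by unique molecular identifiers (UMIs). The material was 3 fresh-frozen sections of melanoma metastases to the brain, 1 section from each of 3 patients. The labels give no treatment or other group among the patients, so all 3 sections form a single group, and they are called section 1, section 2 and section 3.

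The deposited matrices hold raw UMI counts per gene and spot, with no normalization. Per the file headers, the matrices of spots over tissue were written by Space Ranger 1.3.0, and the headers of the matrices of all spots name Cell Ranger 4. Per the submitters' processing notes, Space Ranger was used with genome build GRCh38. The annotation release is not given in the sources used here. A second deposited copy of the tissue matrix of each section was identical to the first, with 0 differing entries. Spot positions and the tissue outline came from the deposited position lists. Each matrix lists 36601 genes, and symbols were taken from it. Gene coordinates are those of the reference gene table for GRCh38.p14, and each gives the span of an annotated gene and not the place of the sequenced tags.

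Spots over tissue numbered 1732, 1302 and 1425 in sections 1, 2 and 3. Analyses of single spots used those with at least 500 UMIs, which left out 311, 158 and 2 spots and kept 1421, 1144 and 1423. No doublet caller was run, since a spot can cover several cells. Levels per section were computed from the summed counts of all tissue spots as CPM (counts scaled to the section's total UMIs), with 95% exact Poisson intervals that cover counting error only.

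Before the data were examined, 17 cell type lists and 17 process lists were fixed, and all their genes were in the files. A spot's list score was the mean over the list of log2(CP10k + 1), where CP10k is the count per 10000 UMIs of the spot. For 2 contrasts the score was averaged over a spot and its adjacent spots, and within each section the 25% of spots with the highest score were compared with the 25% with the lowest. The first contrast used a melanocytic list (PMEL, MLANA, TYR, TYRP1, DCT, GPR143, SLC45A2, TRPM1, SLC24A5 and CDH19) and the second a T-cell list (CD2, CD3D, CD3E, CD3G, CD5, CD7, TRAC, TRBC1, TRBC2, CD8A, CD8B, CD4, IL7R and LCK). Each class is a range of a score and not a cell type. Between 34 and 355 spots per class lay within 0.1 SD of the class limit, and the 355 belong to section 1, where the whole melanocytic-low class had a score of 0 and was drawn at random from the 457 spots with that score. Genes of the list that defined a contrast were left out of its calls and list tests.

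Counts were summed per section and class, giving 6 sums per contrast, and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, its filter on low counts, robust quasi-likelihood fits) with the section as a block and 2 residual degrees of freedom. Both sums of a section come from the same tissue of the same patient, which is where the pairing comes from. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. On simulated counts with 100 genes changed at each fold size, 47% of changes of log2 fold 1 and 84% of log2 fold 2 were recovered in the melanocytic contrast (10377 genes, 11 false among 142 calls), and 64% and 89% in the T-cell contrast (10509 genes, 14 false among 167 calls).

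Spatial structure was measured as Moran's I of log2(CP10k + 1) over adjacent spots, for genes detected in at least 5% of a section's spots, and compared with the highest I of any gene over 100 permutations of the spots. On simulated gradients the limit was set in the same way but over fewer permutations. With a 9-fold difference from edge to edge, 19, 8 and 38 of 100 genes exceeded it in sections 1, 2 and 3. With a 2.25-fold difference none of the 100 did, 0 in each section, so the limit is strict. False calls among unchanged genes numbered 3, 0 and 2. Regions were Leiden clusters from scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, resolution 0.5). Co-location was the Spearman correlation across the spots of a section between unsmoothed list scores, given as the mean over 3 sections. Spots are not replicates, so no p-value was computed from spots.

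The named genes of a contrast were fixed by rule as those past the threshold, with the same direction in all 3 sections and a mean of at least 20 CPM, taking up to 13 higher and 12 lower. Of each list, members past the threshold with the largest fold were named, or otherwise those of smallest p. For spatial structure the rule took the 10 genes with the highest mean I and the 5 highest of each section. For levels it took the 5 genes per section of at least 50 CPM with the largest ratio to the higher of the other sections. Regions were described by the 5 genes of largest fold among those with at least 100 CPM and detected in 25% of the region's spots. Immunoglobulin and T-cell receptor variable segments, genes commonly deleted in a genome, mitochondrial and ribosomal protein genes, long noncoding RNAs and clone-named transcripts were among those not named. The alternatives were DESeq2 1.42.0 (its size factors in edgeR, and its own test), no filter on low counts, no section block, leaving out each section, other score definitions and class sizes, no UMI minimum, spots thinned to 1000 UMIs, and classes and tests drawn from separate random parts of the counts. Near-identical genes such as HBA1 and HBA2, IGHG4 and the other heavy-chain constant genes, TNXB and its pseudogene, MAGEA3 and its relatives, CST2 and its relatives, or GZMB and GZMH can share reads, and their split between copies is uncertain. The values of some genes that the rule names are not reported here. The tissue images were not used here.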

Results

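Spatial gene expression was profiled in 3 brain metastases of melanoma, each from a different patient and each represented by 1 section. The series was deposited with a web application for spatial transcriptomics, and its labels name no comparison between patients. Within a section, spots with high and low scores of melanocytic or T-cell genes can be compared inside the same tissue. Tissue spots held 4795522 UMIs in section 1, 1871773 in section 2 and 9305467 in section 3. The median per spot was 2172, 1113.5 and 6333 UMIs, and the median number of genes per spot was 1247, 788.5 and 3079. Mitochondrial transcripts made up 2.69%, 6.50% and 3.12% of the UMIs.

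The sections differed in how much of the profile came from melanocytic genes and how much from genes of other tissue. The melanocytic list, which holds pigment enzymes and melanosome proteins, reached 815 CPM (95% exact Poisson interval 789 to 840) in section 1, 12152 (11994 to 12311) in section 2 and 8508 (8449 to 8567) in section 3. PMEL, which encodes the fibril protein of melanosomes, was at 248, 6055 and 5259 CPM in sections 1, 2 and 3. MLANA, a melanocyte antigen gene, was at 140, 1844 and 1430 CPM. TYRP1, a melanin synthesis enzyme gene, was at 2.50, 132 and 855 CPM. Over the 3 sections the melanocytic list averaged 7158 ± 5788 CPM (SD, n = 3).

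Section 1 carried most of the brain, plasma cell and connective tissue transcripts. Its astrocyte list stood at 3285 CPM, 28.5 times the higher of the other sections, and GFAP, the filament gene of astrocytes, stood at 987 CPM against 0.534 and 2.90. Its oligodendrocyte list stood at 5711 CPM against 1151 and 432. Its plasma cell list reached 44422 CPM against 114 in section 2 and 4599 in section 3. Collagens and other genes of the fibroblast and matrix list summed to 28593 CPM against 1440 and 3735, and the macrophage list to 14481 CPM against 3737 and 3746. Endothelial genes stood at 1471 CPM against 188 and 143. Genes of neurons stayed low, at 134, 40.6 and 353 CPM, and UCHL1, which is not restricted to neurons, made up 309 CPM of the value in section 3.

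Section 2 held the highest levels of interferon-gamma-induced and class I antigen presentation genes, and section 3 those of metabolism, hypoxia and proliferation. The interferon-gamma list stood at 5995 CPM in section 2, against 2154 in section 1 and 2338 in section 3. The class I presentation list, which includes B2M and the classical HLA class I genes, stood at 41535 CPM in section 2, against 20317 and 10250. Section 3 had 18480 CPM of glycolysis genes against 3850 and 4316, 1606 CPM of hypoxia genes against 529 and 285, and 1538 CPM of cell cycle genes against 289 and 539. Interferon-alpha-induced genes were also highest there, at 8079 CPM against 2196 and 2833. The T-cell list was at 1055, 881 and 135 CPM in sections 1, 2 and 3, and the cytotoxicity list at 396, 680 and 99.2 CPM. With 1 section per patient, no test between patients was possible, and these values describe the sections.

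Of the genes at 50 CPM or more, 310 in section 1, 164 in section 2 and 166 in section 3 stood at least 4 times above both other sections. The largest ratios in section 1 belonged to FABP4, a fatty acid carrier gene of fat and endothelial cells (121 CPM), CES1 (115 CPM), GFAP, the mast cell tryptase gene TPSB2 (59.2 CPM) and ADAMTS15 (140 CPM). In section 2 they belonged to ABCC11 (56.1 CPM), the cystatin gene CST2 (102 CPM), the potassium channel gene KCNJ13 (101 CPM), APCDD1 (547 CPM) and TTN (54.0 CPM). In section 3 they belonged to the cancer-testis genes CTAG2 (222 CPM), MAGEA4 (290 CPM) and MAGEA3 (55.0 CPM), the tight junction gene CLDN1 (70.1 CPM) and MME (59.8 CPM). Most of these had 0 to 10 UMIs in each other section, so the ratios themselves are imprecise: for FABP4 the ratio was 561, with an interval of 155 to 4631.

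**Figure D1:**
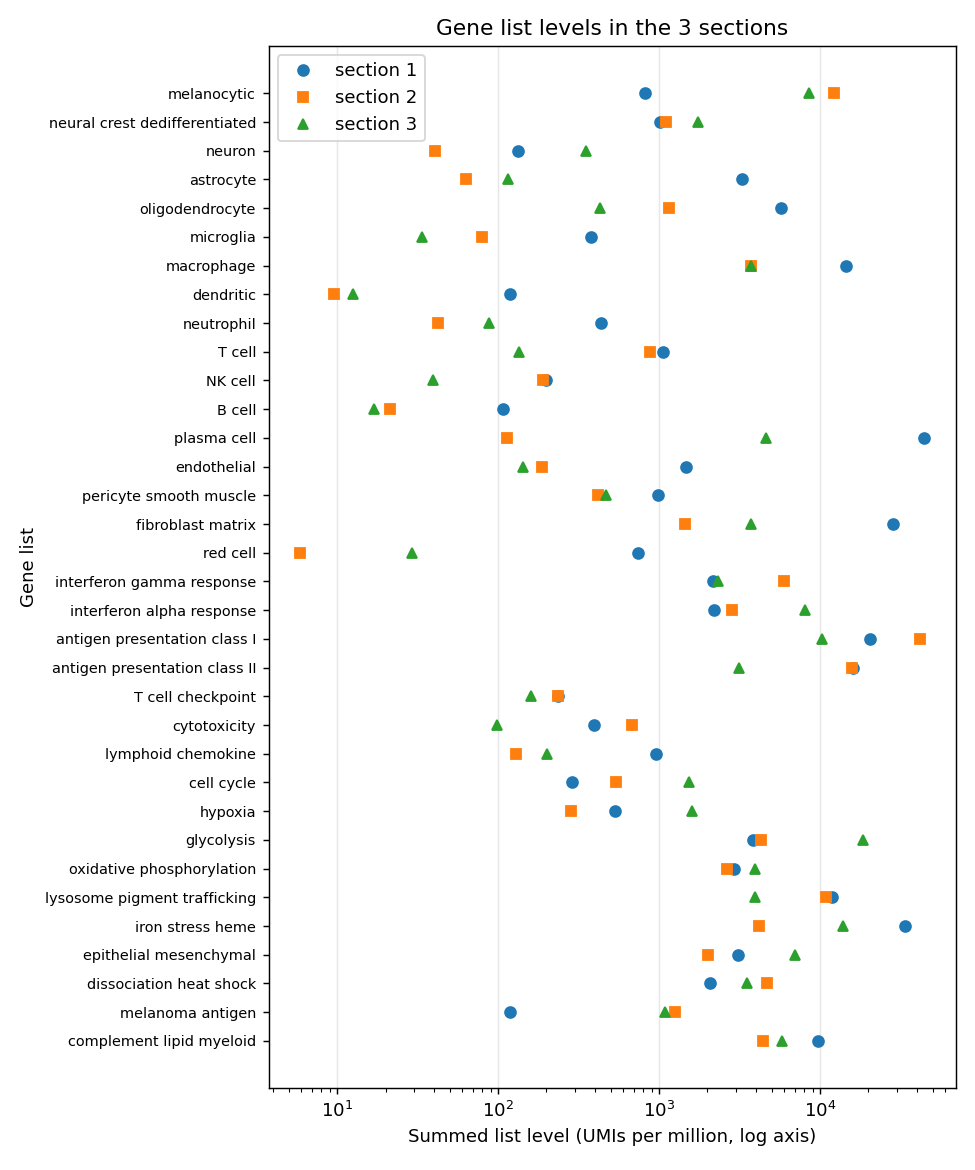
Summed level of each fixed gene list (rows) in the 3 sections, in CPM of all tissue spots on a log axis, with 1 point per section. Section 1 lies far to the left for the melanocytic list (815 against 12152 and 8508) and far to the right for astrocyte and plasma cell genes.

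The layout of each section was first described by clustering its spots into regions. Section 1 split into 4 regions with distinct tissue genes. Its region 3, with 124 spots or 8.73% of the section, was led by PAGE5, DHRS2, MIA, PRSS33 and TYR and held 3333 CPM of the melanocytic list, against 374 CPM in region 2, 80.8 in region 1 and 73.2 in region 4. Region 2, with 362 spots, was led by DNER, STMN4, CNTN2, CNTNAP4 and ELAVL3, genes of neural cells, and held 13653 CPM of the oligodendrocyte list. Region 1, with 849 spots, was led by PI16, CLEC3B, WNT4, FABP4 and INMT. Region 4, with 86 spots, had the haemoglobin genes HBA1, HBA2 and HBB and the gene IGFBP3 among its leading genes.

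Sections 2 and 3 were covered by melanocytic transcripts in every region. Section 2 split into 2 regions of 634 and 510 spots, led by SAMHD1, GPM6A, EIF5B, PRRC2C and SEC62 in region 1 and by WDR6, MMP17, SRSF6, CHKB and UPK3BL1 in region 2, with 11095 and 12977 CPM of the melanocytic list. The median spot of region 1 held 990.5 UMIs and that of region 2 held 1760, so depth differed between them. Section 3 split into 6 regions with 6674 to 9332 CPM of the melanocytic list. Region 2, with 283 spots, was led by NDRG1, SLAMF9, ANGPTL4, SLC2A1 and ADM, among which NDRG1, ANGPTL4, SLC2A1 and ADM belonged to the fixed hypoxia list. Region 3, with 252 spots, was led by the immunoglobulin genes IGLC1 and IGHG1, the B-cell chemoattractant gene CXCL13, the complement gene C1QB and the leukocyte integrin gene ITGB2. Region 4, with 223 spots, was led by NGFR, PAEP, GABARAPL1, CAMK2N1 and KCNN4. Region 6, with 65 spots, was led by INSR, ADGRL4, GJA4, ADGRF5 and EFNB2, at 43.4 to 48.7 times the rest of the section, and genes of blood vessels are among them. Region 1, with 507 spots, had GOLGA4, EIF5B, ZCRB1 and IGLC3 among its leading genes, and region 5, with 93 spots, was led by LTO1, IGHM, SERPINA3, CCND1 and MYEOV. The number of regions depended on the resolution of the clustering, and at a resolution of 1.0 the sections split into 7, 6 and 9 regions. With 1000 variable genes the adjusted Rand index with the regions described, which is 1 for identical regions, was 0.789, 0.467 and 0.255 in sections 1, 2 and 3, so many spots of sections 2 and 3 changed region.

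**Figure D2:**
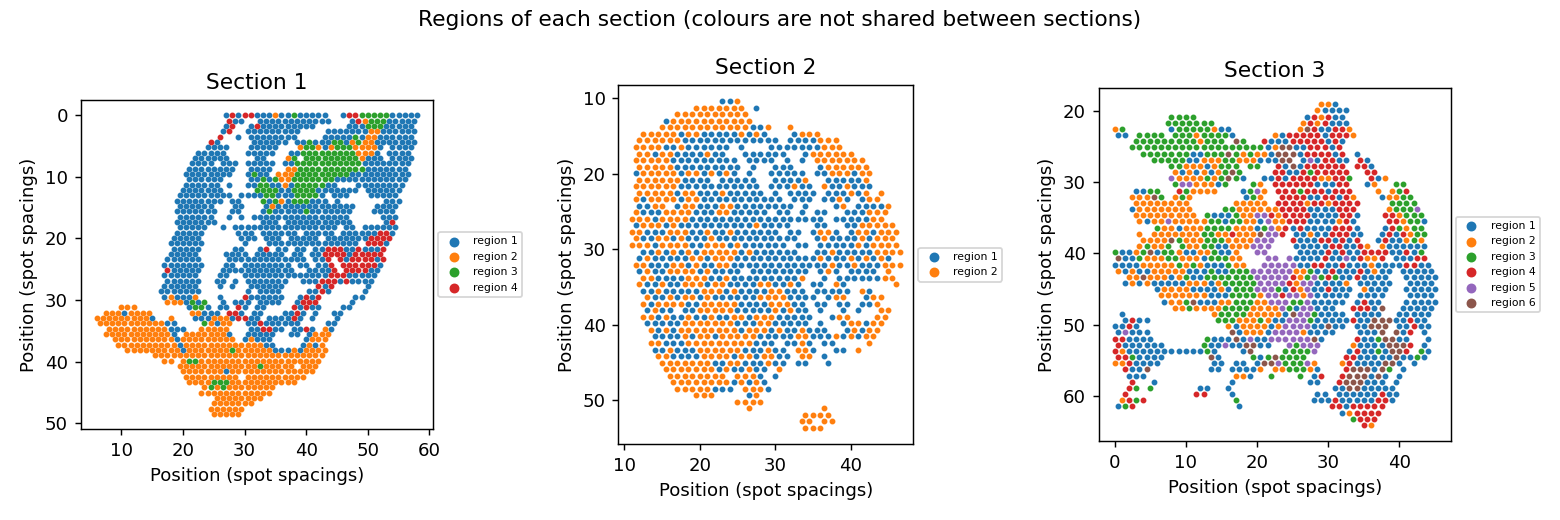
Position of every analysed spot in the 3 sections, with both axes in spot spacings and colours for the regions of each section, which are not shared between sections. In section 1, region 3 forms a compact focus and scattered small groups, and region 2 fills the lower part of the tissue.

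Genes with spatial structure were frequent in sections 1 and 3 and rare in section 2. Moran's I exceeded the highest permuted value for 627 of 8345 genes in section 1, 22 of 5763 in section 2 and 472 of 10498 in section 3. Of 5286 genes measured in all sections, 17 did so in all 3. The highest mean I belonged to the immunoglobulin light chain gene IGKC (0.400 ± 0.297, SD, n = 3), the ferritin gene FTL (0.372 ± 0.367), PMEL (0.331 ± 0.217), the lipid carrier gene APOE (0.323 ± 0.228) and SPP1 (0.315 ± 0.307), followed by S100B, B2M, MLANA, MIA and IFI6. FTL reached 0.759 in section 1 and 0.0294 in section 2, below the permuted limit of 0.112 there. The leading genes of section 1 also included HBA1 (0.707), TF (0.693) and MBP (0.681), and TF and MBP are oligodendrocyte genes of the fixed list. In section 2 the highest values, up to 0.494, belonged to a long noncoding RNA and to mitochondrial transcripts. Apart from such transcripts it was led by HSP90AA1 (0.218), B2M (0.181), PABPC1 (0.175), HLA-B (0.169) and SAMHD1 (0.139), of which B2M, HLA-B, HSP90AA1 and PABPC1 exceeded the limit in all 3 sections. With the same exceptions, section 3 was led by IGKC (0.622), the interferon-induced gene IFI6 (0.554), IGHG4 (0.507), TYRP1 (0.477) and APOE (0.475).

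By list, all 11 measured oligodendrocyte genes and 11 of 12 fibroblast and matrix genes exceeded the limit in section 1, and 9 of 11 plasma cell genes did. In section 3, 8 of 9 plasma cell genes, 6 of 10 melanocytic genes, 8 of 11 glycolysis genes and 6 of 12 hypoxia genes exceeded it, with NDRG1 (0.291) highest in the hypoxia list. Of the T-cell genes, 3 of 12 exceeded the limit in section 1 and 0 of 8 and 0 of 7 did in sections 2 and 3, and their median I was 0.0650, 0.0147 and 0.0675, against 0.0177, 0.0101 and 0.0148 over all genes measured. After thinning each spot to 1000 UMIs, 165 of 3223, 13 of 4010 and 51 of 3931 genes exceeded the limit in sections 1, 2 and 3, over 1256, 713 and 1417 spots.

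Co-location of the lists was measured across the spots of each section. The melanocytic score had a mean rho of 0.00606 ± 0.0772 (SD, n = 3) with the T-cell score, with values of -0.0482, 0.0945 and -0.0281 in sections 1, 2 and 3. After thinning to 1000 UMIs it was negative in all 3 sections, with a mean rho of -0.0888 ± 0.0164. Other lists were then negative in all 3 too, among them fibroblast and matrix (-0.150), cytotoxicity (-0.0659) and neutrophil genes (-0.0613). With scores averaged over adjacent spots, the mean rho with the T-cell score was 0.0516 ± 0.166. The melanocytic score went with the oxidative phosphorylation score (0.293 ± 0.0284) and the cell cycle score (0.227 ± 0.0456) in all sections before thinning. Also positive in all sections, and above the cell cycle score, were lysosome and pigment (0.237), oligodendrocyte (0.235), melanoma antigen (0.233) and complement and lipid scores (0.231). The T-cell score went with the cytotoxicity score (0.254 ± 0.0688), the interferon-gamma score (0.241 ± 0.0812), the lymphoid chemokine score (0.228 ± 0.131) and the macrophage score (0.157 ± 0.0496). Class I presentation (0.254 ± 0.0964), class II presentation (0.216 ± 0.0730) and checkpoint scores (0.173 ± 0.0492) also stood above the macrophage score. The melanocytic score itself was higher in spots with more UMIs, with a mean rho of 0.411 ± 0.123. After the same thinning the mean rho of the melanocytic score was 0.0547 with oxidative phosphorylation and 0.0206 with the cell cycle, where section 2 turned to -0.0306, and that of the T-cell score was 0.122 with cytotoxicity, 0.0741 with interferon-gamma, 0.0931 with lymphoid chemokine and 0.0621 with macrophage genes. The T-cell score then stood at 0.0882 with class I, 0.0833 with class II and 0.0700 with checkpoint genes. The melanocytic score then stood at 0.0610 with oligodendrocyte, -0.00718 with lysosome and pigment, 0.0910 with melanoma antigen and 0.0350 with complement and lipid genes. Among these last lists, only the oligodendrocyte value was positive in all sections. The oxidative phosphorylation value was positive in all sections too, at 0.0833, 0.00946 and 0.0712.

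**Figure D3:**
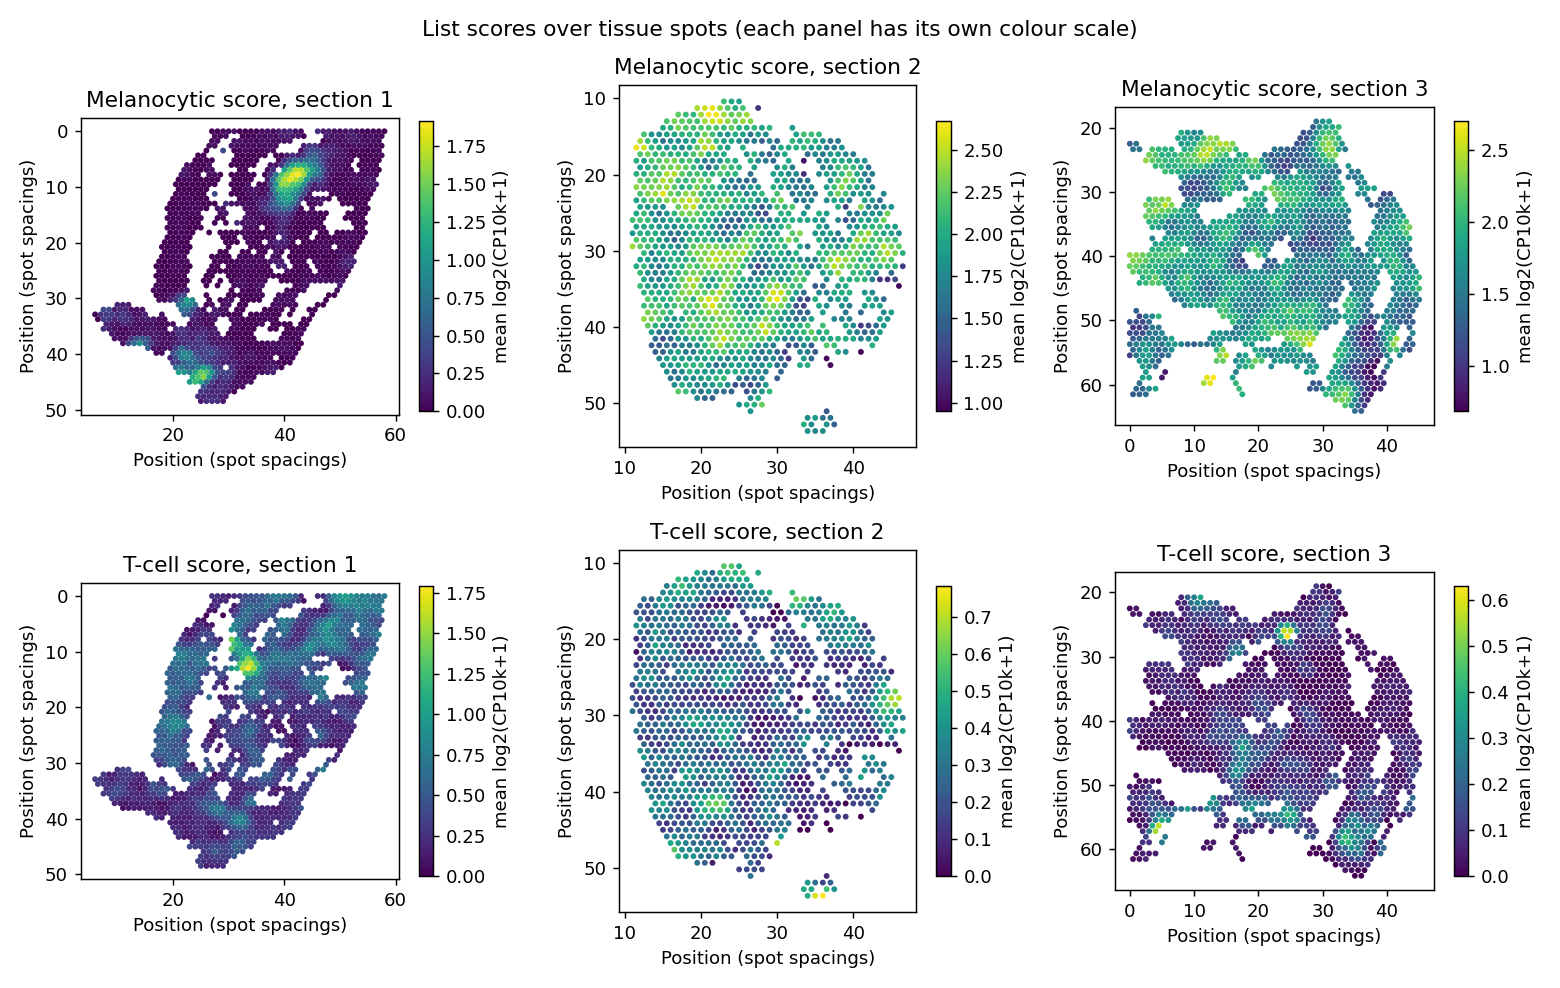
Melanocytic score (upper row) and T-cell score (lower row) over the tissue spots of the 3 sections, with both axes in spot spacings and a separate colour scale per panel in mean log2(CP10k + 1) averaged over adjacent spots. Section 1 shows melanocytic foci in low-scoring tissue, where 457 of 1421 spots had a score of 0, while sections 2 and 3 score above 0 throughout.

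In melanocytic-high spots 6 genes, among them genes of the extracellular matrix, took a smaller share of the UMIs than in melanocytic-low spots of the same section, and no gene was called higher. In edgeR's quasi-likelihood test, 6 of 10807 genes were lower and 0 higher, 767 genes had an unadjusted p below 0.05, and DESeq2 called 7 lower and 0 higher, 5 of them among the 6, while giving no adjusted p for 8176 genes. The matrix genes included POSTN, which encodes periostin (ENSG00000133110, GRCh38 chromosome 13, 37562585 to 37598768), and TNXB, which encodes a tenascin. POSTN fell by 1.77 on the log2 scale (SE 0.271, edgeR adjusted p 0.0306), with values of -1.67 and -1.56 in sections 1 and 3 and 0 and 1 UMIs in the high and low classes of section 2. TNXB had a log2 fold of -2.13 (SE 0.282). Among the others were the alpha-globin gene HBA2 (-2.33, SE 0.284), CPXM1 (-1.69, SE 0.263) and MXRA8 (-1.39, SE 0.226). All 6 had a negative value in 3 of 3 sections, but the 6 genes together rested on only 15 and 21 UMIs in the high and low classes of section 2, against 1967 and 2794 in section 1. The melanocytic list itself, which set the classes, stood at 13658 against 9626 CPM in section 2 and 12218 against 4893 in section 3, and at 2112 against 0 in section 1. The low class of section 2 was thus still rich in melanocytic transcripts. In section 1 the high class had 355 spots and region 3 had 124, so most of the class lay outside that region. Of its spots, 23.4% held no UMI of the list.

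Of 11 measured fibroblast and matrix genes 1 fell in the test over all genes, and 9 were lower when adjusted over the list alone. Their median log2 fold was -1.06, and camera with the preset correlation gave an adjusted p of 2.62e-12. The endothelial list (median -0.85, adjusted p 4.82e-05) and the T-cell list (median -0.56, adjusted p 7.98e-08) were also lower, with 4 and 2 genes lower when adjusted over the list alone. PECAM1, a gene of endothelial junctions, stood at -0.94 and the interleukin-7 receptor gene IL7R at -1.21, and neither passed over all genes. The epithelial-mesenchymal list was lower too (median -0.56, adjusted p 6.54e-06), with 0 of 10 measured genes past the threshold over all genes and 4 over the list alone. The macrophage, hypoxia, cytotoxicity and pericyte lists were lower with adjusted p-values of 0.00113, 0.00113, 0.00113 and 0.00235. The hypoxia list was lower only in section 3, with medians of 0.15, 0.05 and -0.63 in sections 1, 2 and 3. In section 2 the pericyte and epithelial-mesenchymal lists had medians on the higher side, 0.25 and 0.14. Cell cycle genes were higher as a list (median 0.49, adjusted p 3.62e-06), with 0 of 16 genes past the threshold over all genes or over the list alone and TYMS, a nucleotide synthesis gene, at 0.69. The oxidative phosphorylation list was higher with a median of 0.15 and an adjusted p of 0.00270, and the oligodendrocyte list with a median of 0.62 and an adjusted p of 0.00113, the latter from section 1, where its median was 1.62, while it lay slightly below 0 in the others. None of these 11 calls held with an estimated correlation between genes: the camera adjusted p with an estimated correlation was 0.486 for the oligodendrocyte list and 0.414 for each of the others.

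The melanocytic calls changed with the sections used. In edgeR, 0 genes were called without section 2 (686 at an unadjusted p below 0.05), although the 6 genes kept their sign and their median log2 fold was -1.70 there against -1.73 with all sections. The calls were 6 higher and 42 lower without section 1, and 6 higher and 12 lower without section 3, with 1 and 2 of the 6 genes among them, and 0 when classes and tests came from separate random parts of the counts (577 at an unadjusted p below 0.05). In these settings 3, 6 and 3 of the 6 genes were still tested, all with their sign kept, at median log2 folds of -1.38, -1.72 and -1.34. Melanocytic-high spots also held more UMIs, with medians of 3718 against 1816 in section 1, 2248.5 against 798 in section 2 and 7815 against 3951 in section 3.

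In T-cell-high spots 28 genes, among them CXCL13, GZMB, CD6 and CXCL11, took a larger share of the UMIs than in T-cell-low spots, and 8 genes, among them CLDN11, OLIG1 and NGFR, a smaller share. In edgeR's quasi-likelihood test, 28 of 10850 genes were higher and 8 lower in T-cell-high than in T-cell-low spots. The T-cell list itself, which set the classes, stood at 1866 against 404 CPM in section 1 and 1297 against 339 in section 2. In section 3 it stood at 337 against 25.5 CPM, so the high class there lay below the low classes of the other sections. Of the spots in that high class, 20.3% held no UMI of the list. The largest rise was that of CXCL13 (ENSG00000156234, GRCh38 chromosome 4, 77511753 to 77611834), a chemokine gene that attracts B cells, with a log2 fold of 2.74 (SE 0.255, edgeR adjusted p 0.000594) and values of 3.07, 0.97 and 2.65 in the 3 sections. Its level was 78.9 ± 78.1 CPM in the high and 12.8 ± 10.9 CPM in the low class (SD, n = 3). Cytotoxic granule genes rose with it: GZMB by a log2 fold of 2.04 (SE 0.263), GNLY by 2.06 (SE 0.333) and GZMA by 1.69 (SE 0.308). So did the lymphocyte surface genes CD6 (2.29), CD27 (1.70), CD52 (1.86), IL2RG (1.93) and CXCR4 (1.75), the inhibitory receptor gene LAG3 (1.84), and the immunoglobulin constant gene IGHG4 (1.64). The interferon-induced genes CXCL11 (2.01), a chemokine gene, and GBP5 (1.70), a guanylate-binding protein gene, rose as well. All of these were higher in 3 of 3 sections, though section 2 held few UMIs of some in both classes together. It held 6 of IGHG4, 5 of CXCL11, 10 of GNLY, 14 of CXCL13 and 19 of CD52.

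The lower genes included CLDN11 (-0.98, SE 0.174), a tight junction gene of myelin, OLIG1 (-1.58), a transcription factor gene of the oligodendrocyte lineage, NGFR (-1.21, SE 0.162), a receptor gene of neural crest cells, the filamin gene FLNC (-1.10), the desaturase gene SCD5 (-1.81), TMEM144 (-1.61) and HBA2 (-1.36). NGFR was at -1.24 and -1.15 in sections 1 and 3, and section 2 held 4 and 6 UMIs of it in the high and low classes. These 7 genes had a negative value in 3 of 3 sections. In section 2 they held from 2 UMIs (FLNC) to 45 (OLIG1) in both classes together, with 4 of HBA2 and 5 each of SCD5 and TMEM144, so their direction there rests on few counts. Other calls went apart in section 2, and they are named here after their values were seen: LTB, FDCSP and CD48, called higher, held 7, 7 and 9 UMIs there in both classes together and had negative values, and APLP1, called lower, held 0.

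Of the 8 measured cytotoxicity genes 4 rose, and 6 did when adjusted over the list alone (median log2 fold 1.40, camera adjusted p 4.89e-13). Of the 16 interferon-gamma genes 2 rose, and 13 did when adjusted over the list alone (median 0.83, adjusted p 1.40e-25). The lymphoid chemokine list had 2 of 6 genes higher, CXCL13 and LTB, and 5 adjusted over the list alone (median 1.31, adjusted p 2.83e-12). The checkpoint list had 2 of 7 higher, CXCL13 and LAG3, and 4 adjusted over the list alone (median 0.74, adjusted p 5.11e-09). No class II presentation gene passed over all genes, but 9 of 9 did adjusted over the list alone (median 0.55, adjusted p 4.61e-12), with HLA-DQA1 at 0.80, and the class I list was higher with a median of 0.47, an adjusted p of 1.11e-08 and 3 of 7 genes past the threshold over the list alone. The macrophage list was higher (median 0.48, adjusted p 3.25e-05, 5 of 12 genes adjusted over the list alone), with LYZ, the lysozyme gene, at 0.71. Hypoxia genes were lower as a list (median -0.44, adjusted p 2.00e-07), with SLC2A1, a glucose transporter gene, at -0.75, and with 0 of 12 genes past the threshold over all genes and 2 over the list alone. The oligodendrocyte list was lower (median -0.82, adjusted p 3.08e-08), with a median of -1.82 in section 1 and of -0.08 in each of the others. Interferon-alpha, plasma cell, fibroblast and matrix, and cell cycle genes were higher as lists (medians 0.37, 0.88, 0.34 and 0.31), and heat shock and astrocyte genes were lower (medians -0.17 and -0.54), with adjusted p-values of 1.46e-07, 2.52e-05, 0.000523, 0.000579, 0.00387 and 0.00622. In section 2 the median was 0.07 for interferon-gamma, 0.01 for class I, 0.06 for class II, 0.03 for macrophage and -0.04 for hypoxia genes. Those of interferon-gamma genes were 1.09 and 1.06 in sections 1 and 3. Cytotoxicity, lymphoid chemokine and checkpoint medians were 0.31, 0.32 and 0.66 in section 2. Against the direction of their calls, interferon-alpha and astrocyte medians were -0.09 and 1.03 there. Without section 3 the plasma cell list turned to the lower side and did not pass (camera adjusted p 0.982). The melanocytic list did not pass, with a median of -0.20 and an adjusted p of 0.123. None of the 15 list calls held with an estimated correlation between genes: the camera adjusted p with an estimated correlation was 0.272 for the interferon-gamma, interferon-alpha, cytotoxicity, lymphoid chemokine, checkpoint, hypoxia and oligodendrocyte lists. It was 0.293 for heat shock genes, 0.344 for both presentation lists, 0.400 for the macrophage, plasma cell, cell cycle and astrocyte lists and 0.419 for the fibroblast and matrix list.

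**Figure D4:**
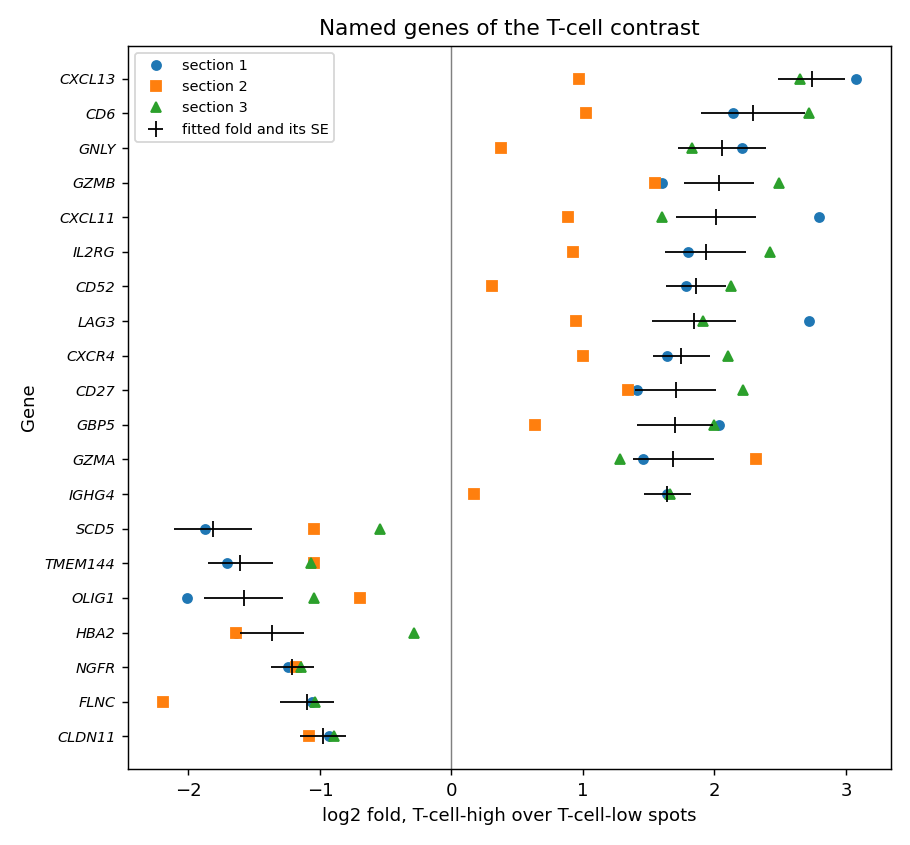
Log2 fold of T-cell-high over T-cell-low spots (horizontal axis) for the named genes (rows), with 1 coloured point per section and a black bar for the fitted fold and its SE. CXCL13 has the largest fitted fold, 2.74, and the points of section 2 lie closer to 0 than the others for most of the named genes called higher.

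DESeq2 called 12 genes higher and 1 lower, all among the genes called by edgeR, and without the section block edgeR called 0 genes, with 10 at an unadjusted p below 0.05. After thinning to 1000 UMIs, 11 genes were higher and 6 lower, and 5 of the 28 higher and 0 of the 8 lower genes remained called, with 17 and 3 of them still tested. Without section 1 the counts were 78 and 7, and without section 3 they were 27 and 57. Among spots above the section's median melanocytic score, 67 genes were higher and 14 lower, and 26 of the 28 higher and 4 of the 8 lower genes remained called. With classes and tests from separate random parts of the counts, 14 of the 28 and 1 of the 8 remained, while 27 and 5 of them were still tested, all with their sign kept, and the median log2 fold of the 27 was 1.38.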

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

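Except for the comparison of off-outline spots near melanocytic-high and melanocytic-low tissue, the tests in this part were chosen after the results were seen, and since all sections form 1 group, the design gives no biological explanation to test.

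Spots outside the tissue outline, which no comparison used, held 36.2% of all UMIs in section 1, 25.7% in section 2 and 29.5% in section 3. Their profile resembled that of the tissue, with a correlation across genes of 0.970, 0.949 and 0.988, and UMIs were fewer farther from the outline (rho -0.561, -0.669 and -0.909 across spots). In section 1, though, they held 0.215 times the tissue's CPM of the melanocytic list and 0.537 times that of the interferon-gamma list. They held 1.31 times that of the fibroblast and matrix list, and their median of 728 UMIs exceeded the count of 22.7% of tissue spots. How much such RNA adds to melanocytic-low spots was not tested. Spread of RNA out of nearby tissue may account for part of the off-outline RNA. The comparison took off-outline spots within 5 spacings of the outline. Those nearest to melanocytic-high tissue held 4.62, 1.12 and 1.33 times the melanocytic CPM of those nearest to melanocytic-low tissue. The lowest of these ratios, 1.12 in section 2, had an interval of 1.01 to 1.23 from counting error only. Tissue left out of the outline could give such ratios too, so they do not tell it from spread RNA. Tissue left out of the outline may account for another part in section 1, where 42 of 2414 spots more than 5 spacings out, or 1.74%, exceeded the tissue median, against 2 of 2840 and 0 of 2380 in sections 2 and 3. How much each contributes stays open, and so does how far spread RNA also evens out differences between tissue spots.

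The 6 genes lower in melanocytic-high spots were weighed against depth, since these spots held more UMIs. Their summed CPM had a mean log2 ratio of -1.69 (SD 0.28, n = 3). After thinning each spot to 1000 UMIs the ratio was -1.19 (SD 0.35), so a fall remained at equal UMIs per spot. The genes were picked for their fall in these same counts, which favours a remaining fall. Thinning also left out spots under 1000 UMIs, and which of these made the ratio smaller was not tested. After thinning, 1 of the 6 genes was still tested, at a log2 fold of -0.41, and 0 remained called, with 4 and 12 UMIs of the set in section 2 and 21 and 40 in section 3. Of the 10 splits of the 6 sums into 3 and 3, 3, the real one included, gave at least the real 6 calls and the highest other gave 483, too few splits for a share under 0.05. The pair of splits with 483 calls parted the classes of only 1 section, and with the section block such a split tests the class difference of that section alone, while among the 4 splits that parted all 3 sections the highest other gave 0.

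The 28 genes higher in T-cell-high spots were weighed in the same way, with median UMIs per spot of 3250 against 2263, 1591 against 960.5 and 5763 against 6367 in the high and low classes of sections 1, 2 and 3. Over the 17 genes still tested after thinning the median log2 fold was 1.60 (SD 0.36) before and 1.20 (SD 0.42) after it, so a rise remained at equal UMIs per spot. These genes were picked for their rise in the same counts, which favours a remaining rise. Here too, spots under 1000 UMIs were left out and the classes drawn anew, so depth was not changed alone. The log2 ratio of the melanocytic list between T-cell-high and T-cell-low spots was -1.25, 0.10 and -0.01 in the 3 sections. The highest had an interval of 0.05 to 0.16 from counting error only. In sections 1 and 3 this argues against T-cell-low spots being poorer in tumour than T-cell-high spots. It does not show that they were tumour. In section 1, 100 of the 355 T-cell-low spots were melanocytic-high, so a part of the class can set its ratio. In section 2, T-cell-low spots included 98 melanocytic-low and 33 melanocytic-high spots, against 53 and 108 among T-cell-high spots. Both scores rose with UMIs there (rho 0.610 and 0.311), so section 2 stays undecided. Of the 10 splits, 3, the real one included, gave at least the real 36 calls and the highest other gave 80, again in a pair that parted only 1 section, too few splits for a share under 0.05, and among the 4 that parted all 3 sections the highest other gave 5. The choice of spots by T-cell genes leaves open which cells carry the transcripts.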

How the results depend on the processing

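The alternatives that left out each section, thinned spots, split the counts or kept spots above the median melanocytic score were added for the gene lists after seeing the data, and all others were planned. The cause of a change was not tested, except that fewer genes were tested after thinning and with split counts. With 3 sections and 2 residual degrees of freedom the counts of calls varied widely. In the T-cell contrast 36 of 36 called genes kept their sign without the block and with DESeq2, and 34, 36 and 35 did without section 1, 2 and 3, where APLP1 and SCD5, and CXCL11, were not tested without sections 1 and 3.

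In the melanocytic contrast (0 higher, 6 lower), no filter on low counts gave 76 and 124, classes of the highest and lowest 1 in 3 spots 1 and 3, no UMI minimum 1 and 11, a score as share of UMIs 2 lower, and thinning 1 lower. Without the section block, with separate parts of the counts and without smoothing, edgeR called 0 lower, with 3, 577 and 903 genes at an unadjusted p below 0.05. Leaving out each section gave 0 to 6 higher and 0 to 42 lower. In the T-cell contrast (28 higher, 8 lower), DESeq2 gave 12 and 1, no filter 196 and 102, no section block 0 and 0 (10 at an unadjusted p below 0.05), a score as share of UMIs 18 and 4, no smoothing 61 and 13, spots above the median melanocytic score 67 and 14, and thinning 11 higher. Separate parts of the counts gave 4 lower and the wider classes 13 lower. Leaving out each section gave 27 to 78 higher and 7 to 57 lower. DESeq2's size factors and leaving out mitochondrial and ribosomal protein genes kept both contrasts within 1.5 times.

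Of the 11 and 15 lists passing camera, 0 and 0 passed with an estimated correlation, 0 and 0 with fry, and 2 and 9 without the section block. Leaving out each section gave 11 to 16 and 14 to 19 lists. The plasma cell list turned to the other direction in the T-cell contrast without section 3, and its camera adjusted p ranged from 1.39e-37 to 0.982 when each section was left out.

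Genes with spatial structure numbered 165, 13 and 51 after thinning, against 627, 22 and 472. A pseudocount of 0.1 gave 988, 55 and 774, no UMI minimum 1120 in section 1 and 76 in section 2, and adding the next ring of spots 103 in section 2. A resolution of 1.0 gave 7 regions in section 1 and 6 in section 2. After thinning, the mean rho of the melanocytic score was -0.0888 with the T-cell score, 0.0206 with the cell cycle and 0.0547 with oxidative phosphorylation, and averaged over adjacent spots the last pair stood at 0.366 and 0.488. The T-cell score after thinning and with averaging had a mean rho of 0.0621 and 0.284 with macrophage, 0.0741 and 0.444 with interferon-gamma, 0.122 and 0.487 with cytotoxicity and 0.0931 and 0.424 with lymphoid chemokine genes. The section with the highest level was the same for 34, 33 and 32 of 34 lists with TMM scaling, without mitochondrial and ribosomal protein genes, and with the mean of spot CPM.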

Other observations

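The rings around the melanocytic focus and the test of the glycolysis list were chosen after results were seen.

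In section 1, interferon-induced transcripts were highest in the melanocytic focus itself and lower with distance from it. The core of region 3 held 6368 CPM of the interferon-gamma list, 3995 of the interferon-alpha list, 28567 of class I presentation genes and 3351 of the melanocytic list. Around the core of region 3 (90 spots of the region with at least 3 adjacent spots of it), the interferon-gamma list stood at 2405 CPM (95% exact Poisson interval 2262 to 2555, counting error only) within 2 spacings, 1501 at 2 to 5, 1168 at 5 to 10 and 1088 farther out. The interferon-alpha list stood at 3082, 2262, 1656 and 1488 CPM over the same rings, and class I presentation genes at 23001, 20301, 18039 and 17447 CPM. T-cell genes stood at 1184 CPM in the core and at 1491, 1106, 979 and 898 CPM in the rings. Other cell types had other courses. Plasma cell genes stood at 58627 CPM within 2 spacings and 35179, 41736 and 45628 farther out, and astrocyte genes were highest at 2 to 5 spacings, with 5333 CPM against 4168, 4428 and 2607. The melanocytic list itself was at 1107, 463, 172 and 155 CPM in these rings, so the nearest ring was not free of its transcripts, and a share of transcripts of region 3 in the rings was not separated from their own level. Off-outline spots of section 1 more than 5 spacings from the tissue outline held 1183.5 CPM of the interferon-gamma list, near the values of the outermost rings. This is 1 section, and no test was made.

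A hypothesis is that glycolysis genes share spots with hypoxia genes in every section. After thinning to 1000 UMIs, rho between the lists was -0.0042, 0.00998 and 0.249 in sections 1, 2 and 3, at percentiles 41.3, 54.7 and 100 of 1000 random lists of like expression, so 1 of 3 sections met it. The hypoxia list had 0.498 and 0.299 UMIs per thinned spot in sections 1 and 2 against 1.60 in section 3, and with so few the hypothesis could not be decided there.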
